A study of Mus musculus with 4 samples.

How the data were processed

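Gene expression was measured in mouse aorta with Affymetrix mouse 430.A 2.0 arrays, which hold 22690 probe sets, 64 of them control probe sets. Female wild-type (WT) mice and disrupting peptide mice (DPM) were 12 to 14 weeks old and were studied 1 week after removal of the ovaries. DPM mice carry a transgene for a piece of estrogen receptor alpha, residues 176 to 253, that keeps the receptor from binding striatin and so blocks its rapid signalling to kinases. Aortas were kept ex vivo for 4 h with 10 nM estradiol (E2) or with ethanol vehicle, and 4 aortas were pooled per sample. The sample titles name 2 replicates for each E2 group and 3 for each vehicle group. The values used here come as 1 level per group, and whether the replicates were separate pools of aortas or repeat arrays of the same RNA is not given in the sources used here. Separate arrays were not analysed here, so no spread between arrays could be computed directly.

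The deposited group levels are on a log2 scale. GCRMA and limma are named in the labels without a version or a role. The authors' deposited table gives, per probe set, the 4 group levels, 3 log2 differences (E2 minus vehicle in WT, E2 minus vehicle in DPM, and the DPM response minus the WT response) and the p_value of each. Those deposited p-values are unadjusted, although the design had allowed for adjusted ones, and no p is given for DPM against WT within a treatment. The deposited differences equalled the differences of the group levels within 6.0e-08, and the group levels in both files were identical. Levels reached 15.27, and 27.3% of probe sets lay within 0.05 of the lowest level in all 4 groups.

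Gene symbols came from the array's probe set annotation, updated by Entrez identifier with a RefSeq gene table on assembly GRCm38.p6, which served for symbols and gene lengths only. A single symbol was given for 20393 probe sets, several for 691 and none for 1606; the last 2 kinds were left out. Each of the 12393 symbols was represented by its probe set with the highest mean level, and the 5151 genes with a log2 level of at least 5 in 1 or more groups were kept. Probe set positions relative to the transgene were not analysed here.

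The standard error (SE) of each log2 difference was recovered from the authors' deposited folds and p. The total degrees of freedom at which the errors of the 3 contrasts keep 1 ratio over 6569 probe sets were 6.44. There the SE of the DPM response was 1.331 times that of the WT response, and the SE of the difference between the responses was 1.665 times that of the WT response. Equal replicate numbers in WT and DPM would give equal errors, so the source of the ratio is not given in the sources used here. The median SE over genes was 0.15 for the WT response, 0.20 for the DPM response and 0.25 for their difference. The median gene therefore needed a fold of 1.29, 1.40 and 1.52, respectively, to reach an unadjusted p of 0.05, and the number of arrays limits this precision. A difference between genotypes within a treatment cannot have a larger error than the difference between the responses, if groups are independent; that error served as an upper bound, a step chosen after the data were seen.

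The deposited p-values were adjusted here by the Benjamini-Hochberg method over the 5151 genes, with a threshold of 0.05, and genes of at least 1.5-fold were counted beside that. For the fixed lists the p-values were also adjusted over the list alone. The rule for named genes, the gene lists, the filter, the thresholds and the comparisons were set before the data were examined. By that rule the 12 genes furthest in each direction were named among those with an adjusted p under 0.05, filled up from those with an unadjusted p under 0.01, or by size alone where no p was given. Up to 4 members of each list with at least 1.5-fold were added, and Esr1, Esr2, Strn, Cav1 and Nos3 were always named. Other list members with an unadjusted p under 0.05 and genes that share a response in both genotypes were named after their values were seen. The lists were estrogen response; immediate early and kinase-responsive; estrogen receptor, striatin and rapid signalling components; smooth muscle contractile; endothelial; extracellular matrix; cell cycle; inflammatory cytokines and adhesion; interferon response; cholesterol synthesis and uptake; hypoxia and glycolysis; heat shock and endoplasmic reticulum stress; circadian clock; Notch signalling; adipocyte; macrophage and leukocyte; cardiac and skeletal muscle; mesothelial and epithelial; fibroblast; nerve and Schwann; blood cell; and sex check.

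Each list's median log2 difference was placed among the medians of 10000 random lists of equal size matched on mean level in 10 bins. The 2.5 and 97.5 percentiles served as bounds. Members of a list vary together, so this describes these samples and is not a test; 56 of 105 medians lay outside the bounds.

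The recovery was tested on simulated data with 5150 genes, 200 of them changed. The true degrees of freedom, 8.65, were recovered as 8.65, and 100% of recovered errors lay within 1% of those from limma. The simulation gave all genes 1 ratio of DPM to WT error and limma the matching weights. That recovery was therefore largely fixed in advance and checks the computation only. In the deposited values the log2 ratio of both errors had a standard deviation of 4.1e-07 over probe sets. At an adjusted p under 0.05, 54% of 1.5-fold and 84% of 2-fold changes were found in the simulated WT contrast, and 12 of the 178 genes called were unchanged. The simulation had more degrees of freedom than the 6.44 of the data and held changes of up to 4-fold. These shares may therefore be too high for the data.

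Alternatives tried were no filter on level, a minimum level of 7, the mean over a gene's probe sets, leaving out probe sets whose names mark shared sequence (ending in _x_at or _s_at), centring each comparison on the median of all genes, quantile normalization of the 4 group columns, adding 32 on the linear scale before taking logs, and a threshold of 2-fold. Alternatives chosen after the data were seen were an unadjusted p under 0.05 together with 1.5-fold, the bound on p for the genotype comparisons, noise added to the WT differences up to the error in DPM, both scalings for list members and shared genes at an unadjusted p under 0.05, and leaving the cardiac list out of the correlation. Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for the simulation.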

Results

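Expression was measured with oligonucleotide arrays in aortas of ovariectomized female mice kept ex vivo for 4 h with estradiol (E2) or vehicle. WT aortas and aortas of DPM mice, which express a peptide that separates estrogen receptor alpha from striatin, gave 4 groups. The titles name 2 replicates for each E2 group and 3 for each vehicle group, with 4 aortas pooled per sample, and 1 level per group was available for use here. Median log2 levels of the 5151 genes kept were 6.84 in WT with E2, 6.84 in WT with vehicle, 6.89 in DPM with E2 and 6.81 in DPM with vehicle. Values after ± are standard errors recovered from the authors' deposited folds and p, and all differences are log2 values. Xist stood at levels of 9.72 to 10.16 in the 4 groups, and the Y-linked genes of the sex check list did not reach the minimum level in any group. Esr1 lay between 2.31 and 2.33 and Esr2 at the lowest level of the array in every group, and Strn lay between 3.09 and 3.33.

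The first comparison asks what E2 does in WT aorta within 4 h. Most genes of the immediate early, interferon and endothelial lists were higher with E2, and most of the inflammatory, extracellular matrix and hypoxia and glycolysis lists were lower. Tmod1, which caps the pointed ends of actin filaments, was higher by 1.65 ± 0.23. Mast2, a microtubule-associated kinase gene, was higher by 0.84 ± 0.07 with the smallest adjusted p of the comparison (adjusted p = 0.0512), and Sfrp1, a secreted inhibitor of Wnt signalling, was higher by 1.16 ± 0.18. Mmp3, the matrix protease stromelysin, was lower at -1.19 ± 0.31, and Prg4, which encodes lubricin, was lower at -1.17 ± 0.23.

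Of the 36 measured immediate early and kinase-responsive genes, 25 were higher in WT with E2, and 7 had an unadjusted p under 0.05, all 7 of them higher. Fosb (1.05 ± 0.24), Fos (0.63 ± 0.23), Atf3 (0.63 ± 0.22) and Klf2 (0.68 ± 0.19), a flow-responsive transcription factor of endothelium, were among the 7, with Fosl2, Jund and Egr1 (0.28 ± 0.07). Rgs2 was lower at -0.73 ± 0.38. None passed when adjusted over the list alone, and none over all genes tested. The list's median difference was 0.15, above those of all 10000 matched random lists. Outside the list, Elk3, an ETS factor that responds to serum and kinase signals, was higher by 0.95 ± 0.16, and Tiparp, a gene induced through the aryl hydrocarbon receptor, by 1.06 ± 0.28.

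Of 16 interferon response genes, 15 were higher in WT with E2. Ifit1 (1.62 ± 0.48), Ifit2 (1.13 ± 0.24), Ifit3 (0.88 ± 0.29), Rsad2 (0.79 ± 0.23) and Rtp4 (0.65 ± 0.20) had an unadjusted p under 0.05. The 1 gene that passed when adjusted over the list alone was Ifit2 (adjusted p = 0.0425), and 0 passed over all genes tested by limma's p. Oasl2 was higher by 1.07 ± 0.47. Of 19 endothelial genes, 17 were higher, with a list median of 0.21. Icam2 (0.68 ± 0.13), the angiopoietin receptor gene Tek (0.63 ± 0.17) and Vwf (0.50 ± 0.14) had an unadjusted p under 0.05, and Icam2 passed when adjusted over the list alone (adjusted p = 0.0324) but not over all genes.

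Of 29 genes for inflammatory cytokines and adhesion, 23 were lower in WT with E2, with a median of -0.11. The leukocyte adhesion molecule gene Sele (-0.97 ± 0.26), the chemokine genes Cxcl5 (-0.80 ± 0.21), Cxcl2 (-0.56 ± 0.20) and Ccl2 (-0.49 ± 0.14), and Il6 (-0.31 ± 0.06) had an unadjusted p under 0.05. Il6 alone passed when adjusted over the list alone (adjusted p = 0.0399), and 0 of the 29 passed over all genes tested. Il1b was lower at -0.69 ± 0.39. Of 39 extracellular matrix genes, 26 were lower, with a median of -0.09. Mmp3, the protease inhibitor gene Timp1 (-0.83 ± 0.25), Tnc (-0.40 ± 0.07), which encodes tenascin C, and Fn1 (-0.25 ± 0.10) had an unadjusted p under 0.05 downwards, and Thbs2 (0.26 ± 0.10) had it upwards, though not when quantile normalized (0.25). Tnc passed when adjusted over the list alone (adjusted p = 0.0334), and 0 of the 39 over all genes. Of 24 hypoxia and glycolysis genes, 18 were lower (median -0.15); Egln3 (-0.60 ± 0.18), Car9 (-0.53 ± 0.18), Ldha (-0.21 ± 0.08), Tpi1, Pgk1 and Ndrg1 had an unadjusted p under 0.05 downwards, and Hk1 (0.35 ± 0.12) upwards. None of the 24 passed when adjusted over the list alone or over all genes tested.

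The estrogen response list had a median of 0.12 over 20 genes, with Cxcl12 (0.30 ± 0.12) and Errfi1 (0.27 ± 0.10) higher and Fhl2 (-0.42 ± 0.16) and Cited2 (-0.33 ± 0.13) lower at an unadjusted p under 0.05, of which Errfi1 no longer reached it when quantile normalized (0.19). Among 25 genes for the receptor, striatin and rapid signalling, Pik3r1 (0.63 ± 0.17) and Map2k1 (0.39 ± 0.12) were higher at that level; Cav1 differed by -0.15 ± 0.12 and Nos3 by 0.21 ± 0.19. Of the smooth muscle list, Myocd, the coactivator of contractile genes, was lower at -0.53 ± 0.19, and of the heat shock list Cryab was higher by 0.58 ± 0.15. In the fibroblast list, Gdf10 was higher by 0.60 ± 0.25, a call that ended when centred or quantile normalized with a difference of 0.59 in both, and Penk lower at -0.58 ± 0.22. None of the members of these 5 lists passed when adjusted over the list alone. Medians in WT were -0.07 for smooth muscle, -0.02 for heat shock, 0.17 for fibroblast (14 of 16 genes higher), 0.15 for clock, 0.14 for leukocyte and -0.01 for mesothelial genes. Of 7 mesothelial and epithelial genes, 3 were higher and 4 lower. Krt18 was lower at -0.44 at an unadjusted p under 0.05. Upk3b stood at 1.93, and at 1.53 at another probe set, without reaching that p. No member of that list passed when adjusted over the list alone.

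Further genes named by the rule in WT were Sprr1a (1.39 ± 0.38), Tstd2 (1.12 ± 0.24), Desi2 (1.08 ± 0.20), Zcchc10 (1.00 ± 0.25), Calhm5 (0.99 ± 0.15) and Caskin2 (0.98 ± 0.26) upwards. Downwards, Rasal2, a Ras GTPase-activating protein gene, was at -0.98 ± 0.15, Eva1c at -0.76 ± 0.15, and Mrtfa, a partner of serum response factor, at -0.60 ± 0.10. Zyg11b, Scamp3, Pex16, Mrpl15 and Scaf11 lay between -0.56 and -0.52, but another probe set of Scaf11 stood at 0.06 and the other 3 of Mrpl15 between -0.20 and -0.08. At 1.5-fold, 76 genes were higher and 42 lower. At an adjusted p under 0.05 from the deposited limma p there were 0 genes; at an unadjusted p under 0.05 there were 350 (214 higher and 136 lower, against 197 and 151 centred and 181 and 183 quantile normalized) where chance gives 257.6, and under 0.01 there were 105 (68 higher and 37 lower). With no gene past the adjusted threshold, each of these genes is a difference with its error and not an established change.

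**Figure D1:**
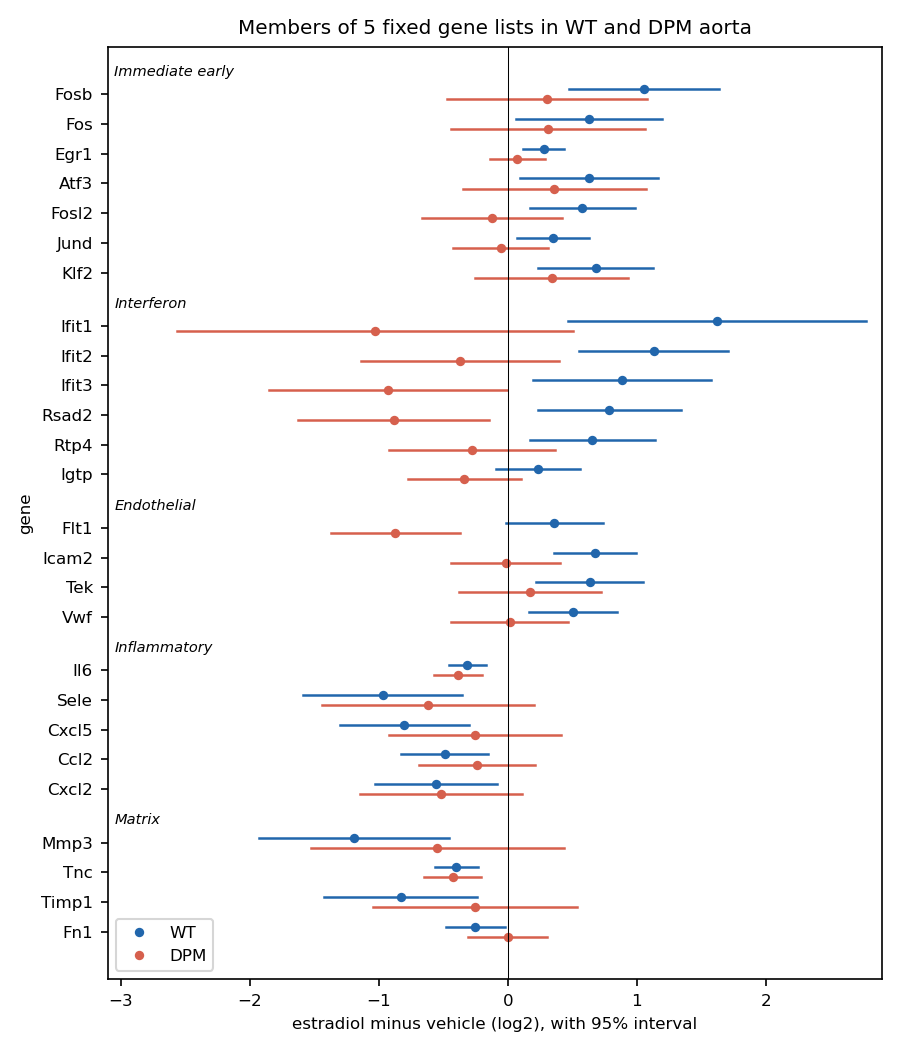
Differences between E2 and vehicle (log2) in WT and DPM aorta for members of the immediate early, interferon, endothelial, inflammatory and matrix lists, 1 point per gene and genotype, with bars for 95% intervals recovered from the authors' deposited folds and p. The 6 interferon genes drawn lie above 0 in WT and below 0 in DPM.

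The second comparison asks which responses to E2 remain in DPM aorta. Tmod1 was higher by 1.17 ± 0.31 here too, and Kcnj8, a pore subunit of ATP-sensitive potassium channels in vascular muscle, was higher by 1.02 ± 0.26. Calhm5 was higher by 0.98 ± 0.20, Il17ra, an interleukin 17 receptor gene, by 0.81 ± 0.15, and Ezr, which encodes the membrane linker ezrin, by 0.79 ± 0.19. Flt1, a receptor for vascular endothelial growth factor, was lower at -0.87 ± 0.21, and Tnc (-0.43 ± 0.09) and Il6 (-0.39 ± 0.08) were lower.

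Siah1a, which encodes a ubiquitin ligase, rose by 0.17 ± 0.01 (adjusted p = 0.0112) and was the 1 gene past the adjusted threshold in DPM. The call ended when the comparison was centred on the median of all genes, 0.08, which left 0.08, or quantile normalized (0.11), and another probe set of Siah1a stood at -0.01. Ciao2a (0.76 ± 0.08), an iron-sulfur assembly gene, Abcd3 (0.70 ± 0.15), a peroxisomal transporter gene, Rras2 (0.70 ± 0.15), Zfp35 (0.66 ± 0.17) and Lmo2 (0.61 ± 0.17) were higher. Mrpl15 was higher by 0.73 ± 0.12 at its highest probe set, while its other 3 probe sets lay between -0.15 and 0.00. Trio (-0.82 ± 0.22, with another probe set at -0.21) and Gbp6 (-0.76 ± 0.21), an interferon-induced GTPase gene, were lower.

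In DPM with E2 the cardiac list had a median of -2.67. Of the RNA quality controls, Gapdh stood at -1.21 ± 1.11 (5' end), -0.64 ± 0.60 (middle) and 0.10 ± 0.11 (3' end), against 0.54, 0.28 and -0.03 in WT. In the same order the beta-actin controls stood at -0.58 ± 0.39, -0.53 ± 0.43 and -0.37 ± 0.31, against -0.41, -0.44 and -0.24 in WT. None of these controls had an unadjusted p under 0.05 by the deposited limma p. Of the 16 interferon genes, 15 were lower in DPM with E2, with a median of -0.44. Ifit3 (-0.93 ± 0.38) and Rsad2 (-0.88 ± 0.31) had an unadjusted p under 0.05; Ifit1 stood at -1.03 ± 0.64 and Iigp1 at -0.64 ± 0.46. The endothelial median was -0.11, with 12 of 19 genes lower, 14 when centred. Flt1 and Emcn (0.58 ± 0.22) had an unadjusted p under 0.05, Emcn no longer when centred (0.50) or quantile normalized (0.53), and Eng stood at -0.61 ± 0.37. Among the 36 immediate early genes 0 had an unadjusted p under 0.05 by the deposited limma p; Fosb was at 0.31 ± 0.32, Junb at -1.06 ± 0.86 and Plaur at -0.83 ± 0.55, and the median of 0.03 turned negative when centred. Among inflammatory genes 21 of 29 were lower, 24 when centred, and Il6 had an unadjusted p under 0.05; Nfkb2 stood at -0.65 ± 0.52. The inflammatory median was -0.17. Of the matrix genes 23 of 39 were lower, 29 when centred (median -0.07), and Tnc and Thbs2 (0.40 ± 0.14) had it in the directions seen in WT, Thbs2 no longer when centred (0.32). No member of these 5 lists passed in DPM when adjusted over the list alone.

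The hypoxia gene Car9, a carbonic anhydrase gene, was lower at -0.88 ± 0.24 in DPM, while the list's median of 0.01 turned negative when centred. Efemp1 of the estrogen response list was higher by 0.96 ± 0.39, Map2k1 by 0.48 ± 0.17, the chaperonin gene Hspe1 by 0.27 ± 0.07 and the clock gene Nfil3 by 0.69 ± 0.27, each at an unadjusted p under 0.05. When centred, that call was kept for Hspe1 (0.19) and ended for Efemp1 (0.88), Map2k1 (0.40) and Nfil3 (0.61); quantile normalized, Map2k1 kept it. The medians of the estrogen response (0.05), rapid signalling (0.04) and circadian clock (0.04) lists turned negative when centred. The heat shock median was 0.16, with 20 of 26 genes higher and 15 when centred. Smooth muscle genes had a median of -0.04, with 16 of 23 lower and 20 when centred. Smtn of that list was lower at -0.38 ± 0.15, and Des stood at -0.86 ± 0.42. The leukocyte genes Cd53 (1.03 ± 0.40) and Csf1r (0.42 ± 0.16) were higher at an unadjusted p under 0.05, both no longer when centred (0.95 and 0.34), while Cd53 kept it when quantile normalized. Their list's median was 0.26, and that of the 7 mesothelial genes was 0.45. Of those 7, 5 were higher, among them Upk3b (1.17) and Krt19 (1.00), and 2 lower, with 0 at an unadjusted p under 0.05. The adipocyte list, with 0 of 23 members at an unadjusted p under 0.05 in either genotype, had a median of 0.24 in DPM and -0.16 in WT; Pck1 was at 1.05 ± 0.97 and Ucp1 at 0.69 ± 0.67 in DPM. Clec3b of the fibroblast list was lower at -2.05 ± 0.84, and that list's median of 0.01 turned negative when centred.

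Genes of heart muscle had wide errors in DPM. Nppa (-4.43 ± 1.39), which encodes atrial natriuretic peptide, Myl7 (-4.39 ± 1.81) and Tnni3 were lower at an unadjusted p under 0.05. With E2, Tnni3 lay within 0.05 of the lowest level of the array, so the size of its difference is a lower bound. Nppa stood at 2.38 and Myl7 at 2.83 with E2, where signal over background is low, so the sizes of their differences are uncertain too. Myh6 (-4.19 ± 1.80) and Actc1 (-3.66 ± 1.59) did not reach that p. The 10 measured genes of the cardiac and skeletal muscle list had a median of -2.67 in DPM and -0.10 in WT, and none passed when adjusted over the list alone. Actc1, Mb, Myh6, Myl7, Nppa, Ryr2 and Tnni3 passed the filter on level through DPM vehicle alone, so the DPM median leans downwards. The authors' levels of 8 of the 10 were highest in the DPM vehicle group by at least 1.5-fold over WT vehicle, so the cardiac genes move with the vehicle group of DPM in every comparison that uses it.

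At 1.5-fold, 116 genes were higher and 87 lower in DPM with E2; the split was 69 and 123 centred and 83 and 107 quantile normalized. At an unadjusted p under 0.05 there were 268 genes (218 higher and 50 lower), where chance gives 257.6. The count became 219 (100 higher and 119 lower) when centred and 210 (131 and 79) when quantile normalized. Both lie below the count from chance and differ in their split, so no direction is given for the response as a whole. Under 0.01 there were 61 genes, 56 higher and 5 lower, where chance gives 51.5. The split under 0.01 was 25 and 19 centred and 34 and 13 quantile normalized. The 18 hybridization control probe sets were all lower in the E2 group of DPM than in its vehicle group, with a median of -0.47, against 0.02 in WT.

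**Figure D2:**
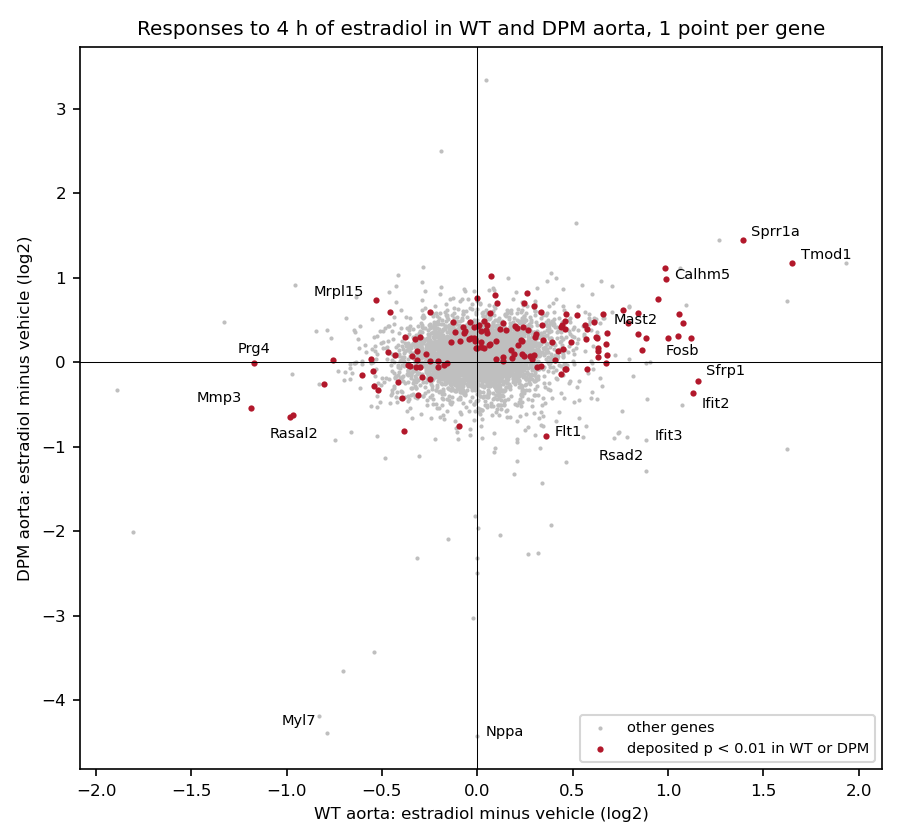
Difference between E2 and vehicle (log2) in WT aorta on the x axis and in DPM aorta on the y axis, 1 point per gene for 5151 genes, with genes at a deposited p under 0.01 in WT or DPM in red. Across genes the correlation was 0.135; genes are not independent replicates.

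The third comparison tests the difference between both responses, which is the test of whether the peptide changes the effect of E2. The median difference of the interferon list was -0.75, and in the same contrast that of the cardiac list was -2.63. The Gapdh 5' control stood at -1.76 and the beta-actin 5' control at -0.17, neither with an unadjusted p under 0.05 by limma. The response of Ifit3 was lower in DPM by a difference of -1.81 ± 0.48, that of Rsad2, the antiviral gene for viperin, by -1.67 ± 0.38, and that of Ifit2 by -1.50 ± 0.40. In all, 15 of 16 interferon genes had a lower response in DPM and 6 had an unadjusted p under 0.05; 3 genes, Ifit2, Ifit3 and Rsad2, passed when adjusted over the list alone (adjusted p = 0.0434 each) and 0 over all genes tested by the deposited limma p. Ifit1 differed by -2.65 ± 0.80 and Oasl2 by -1.59 ± 0.77.

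Lists of other cell types also moved in this contrast. The adipocyte list had a median difference of 0.47, with 20 of 23 responses higher in DPM. The fibroblast list had one of -0.18, with 10 of 16 lower. Of 19 endothelial genes, 16 had a lower response in DPM, with a median of -0.37, beside the -2.63 of the cardiac list. Flt1 (-1.23 ± 0.26) passed when adjusted over the list alone (adjusted p = 0.049) and not over all genes, Icam2 (-0.69 ± 0.22) had an unadjusted p under 0.05, and Eng (-0.90 ± 0.47) and Pecam1 (-0.82 ± 0.45) did not. Sfrp1 (-1.38 ± 0.30), Wwc2 (-0.54 ± 0.10), Mast2 (-0.52 ± 0.11) and Gas6 (-0.50 ± 0.14), a ligand of TAM receptors, also had lower responses in DPM, though the other 2 probe sets of Wwc2 stood at -0.20 and 0.04. Of the immediate early genes, Fosl2 (-0.70 ± 0.28) had an unadjusted p under 0.05 and Fosb (-0.75 ± 0.40) did not; 22 of 36 had a lower response, 26 when centred. So Fosb passed an unadjusted p of 0.01 in WT and not in DPM, but its responses were not shown to differ.

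Higher responses in DPM were seen for Rcbtb2 (1.32 ± 0.33), Dus1l (1.05 ± 0.15), a tRNA dihydrouridine synthase gene, Ltbp2 (0.85 ± 0.20), Ciao2a (0.76 ± 0.10), Dhx32 (0.67 ± 0.13) and Dctn5 (0.60 ± 0.10). Gfm1 (0.60 ± 0.11), a mitochondrial elongation factor gene, Lyst (0.60 ± 0.12), Prelid3b and Nol11 followed. Mrpl15 differed by 1.26 ± 0.15, with its other probe sets between -0.04 and 0.21. Siah1a differed by 0.17 ± 0.01 (adjusted p = 0.0454), the 1 gene past the adjusted threshold, and that call ended when centred (0.10) or quantile normalized (0.12). Among the lists, Cd53 (1.45 ± 0.49), Krt18 (0.88 ± 0.25), Nfil3 (0.86 ± 0.34) and Hspe1 (0.28 ± 0.08) had an unadjusted p under 0.05, Nfil3 no longer when centred (0.79). Prg4 differed by 1.16 ± 0.38. Mmp3 differed by 0.64 ± 0.51 and did not reach an unadjusted p of 0.05.

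Cholesterol synthesis genes had a median of -0.04 in WT and 0.26 in DPM over 12 genes, with Cyp51 at a difference of 1.03 ± 0.46, but 0 had an unadjusted p under 0.05 by limma. The list's DPM median turned to -0.05 with the mean over probe sets. Notch signalling genes had medians of 0.24 and 0.16, with Heyl at 0.59 ± 0.26 in WT. Cell cycle genes, of which 8 of 41 were measured, had medians of -0.02 and 0.09. Nerve (-0.04 and -0.09) and blood cell lists (0.05 and -0.17) had 3 measured genes each. Across all genes, 196 responses were higher and 160 lower in DPM by 1.5-fold (135 and 193 centred, 157 and 179 quantile normalized). An unadjusted p under 0.05 was found for 216 (163 higher and 53 lower, against 88 and 96 centred and 119 and 71 quantile normalized), and 257.6 are what chance gives.

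Both responses were also set beside each other gene by gene. At an unadjusted p under 0.05, 43 genes were higher in both genotypes, 6 lower in both and 10 opposite in sign; centred, the counts were 30, 11 and 6. Independent responses would give 9.1, 1.3 and 7.8 as deposited, so the number of opposite genes is near that from chance. Both p use 1 error per gene, so genes with small errors can pass in both without a shared response. Small errors alone would raise the number of opposite genes as well. The 10 opposite genes against 7.8 argue against small errors as the whole account of the 43 and 6. The higher genes that stayed when centred included Tmod1, Calhm5, Caskin2, Elk3, Lmo2 and Mast2, the muscle transcription factor gene Mef2a (0.84 ± 0.12 in WT and 0.58 ± 0.16 in DPM), Foxo1 (0.46 ± 0.08 and 0.39 ± 0.10) and the chemokine receptor gene Ackr3 (0.27 ± 0.05 and 0.38 ± 0.07). The 6 lower genes were Car9, Csnk2a1, Il6, Rasal2, Tnc and Zeb1. The 6 opposite genes that stayed when centred were Dus1l, Gfm1, Ifit3, Mrpl15, Mrpl22 and Rsad2. The 68 genes higher in WT at an unadjusted p under 0.01 had a median of 0.50 in WT and 0.26 in DPM, with 59 of one sign in both. For the difference, 16 of the 68 had an unadjusted p under 0.05. The 37 lower genes had medians of -0.37 and -0.03, with 21 of one sign in both and 22 with an unadjusted p under 0.05 for the difference. The groups were picked for their WT values, so the WT medians lean away from 0. The difference holds the same WT values, so its low p-values in these groups are no separate support. All genes had a median of 0.08 in DPM, which by itself favours shared rises over shared falls. Across all 5151 genes Pearson's r was 0.135 and Spearman's rho 0.097; genes are not independent replicates.

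The fourth comparison sets DPM against WT in vehicle, without added E2. Heart muscle genes stood far higher in DPM: Nppa by at least 4.50, Myl7 by 4.11, Myh6 by 3.85, Actc1 by 3.47, Sln by 3.37, Tnnt2 by 3.05 and Tnni3 by at least 3.00. Their errors are at most 1.26 for Tnni3 and 2.26 for Myl7. Secretory genes of airway epithelium, Scgb1a1 (at least 4.11), Bpifa1 (at least 3.90), Scgb3a2 (at least 3.28), Cyp2f2 (2.98) and Scgb3a1 (at least 2.86), also stood higher, with errors of at most 4.18 for Scgb1a1. The bounds are for genes whose WT vehicle level lay within 0.05 of the lowest level of the array, or, for Scgb3a1, was equal in both WT groups. All 12 genes lay under the minimum level of 5 in WT vehicle, where signal over background is low, so the sizes are uncertain. Of the cardiac list all 10 measured members, out of 32 listed, were higher in DPM and 8 of them by 1.5-fold. Actc1, Mb, Myh6, Myl7, Nppa, Ryr2 and Tnni3 reached the minimum level of 5 in DPM vehicle alone. The filter thus favoured members high in that group, so this count and the list's medians are no separate support.

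Interferon genes were higher in DPM vehicle in 15 of 16 cases, 9 of them by 1.5-fold, with a median of 0.70, in the group where the heart and airway genes above also stood highest; the leukocyte list had a median of 0.13 there. The mesothelial and epithelial list had a median of 0.54, with 5 genes higher and 2 lower. Of the 5' controls, Gapdh stood at 0.67 and beta-actin at 0.08. Ifit1 was higher by 2.23 with an error of at most 0.80, Ifit3 by 1.43 and Oasl2 by 1.38. The chemokine gene Cxcl10 was higher by 1.13 (error at most 0.55), the antigen presentation gene Cd74 by 0.86 and H2-Ab1 by 0.71. Adipocyte genes were lower in 19 of 23 cases, with a median of -0.35 and Retn at -0.76, Thrsp at -0.60 and Scd1 at -0.59. Hypoxia and glycolysis genes were lower in 21 of 24 cases (median -0.25), among them Car9 at -0.63. Lowest relative to WT were Edn2 (-2.24), an endothelin gene, Acaa1b (-1.26), Bcam (-1.24), Trbv1 (-1.22), Dapk2 (-1.17), Amy1, Arntl, Mbd1, Nt5c2, Ccn5, Tmem45b and Syne2 (-1.03). That ranking used size alone, without regard to errors, so a large size does not set a gene apart from 0. Clec3b (2.44) and Pi16 (1.03) of the fibroblast list were higher. At 1.5-fold 94 genes were higher and 73 lower. The table used here gives no p for this comparison. With the bounded error 55 genes had an unadjusted p under 0.05 and 0 passed when adjusted. The bound is strict: in the simulation 0.6% of unchanged genotype differences had such a p. The 55 are therefore not comparable with the 257.6 that chance gives for a deposited p.

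**Figure D3:**
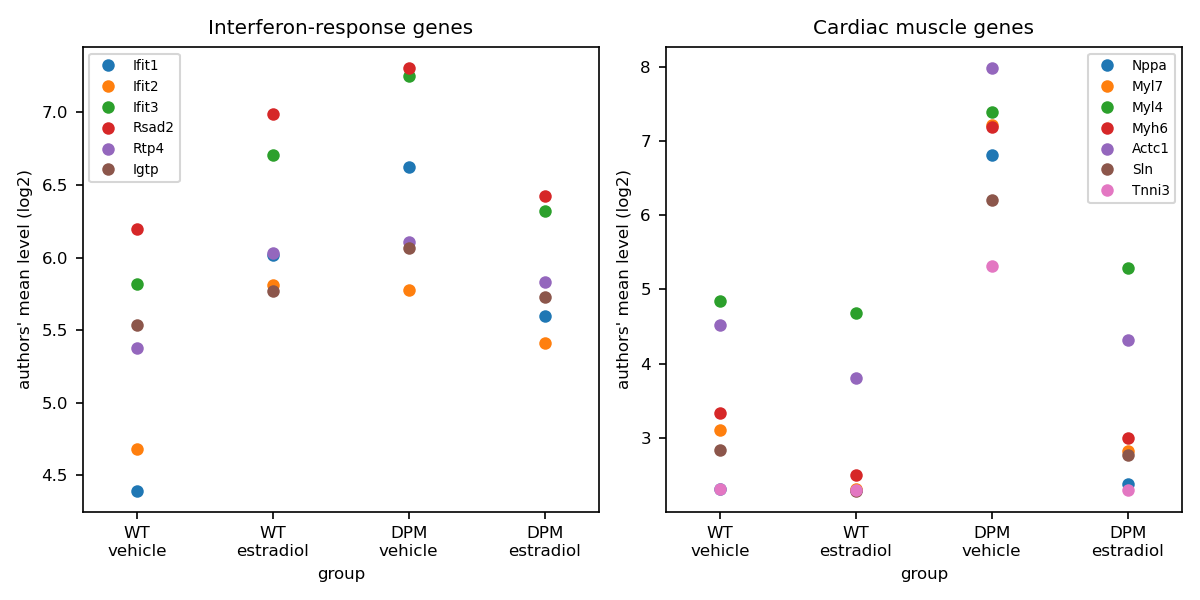
Group levels (log2) in the authors' deposited data for selected genes in the 4 groups, WT and DPM with vehicle or E2; each point is 1 group level and no error is drawn. Nppa and Myl7 stand higher in DPM vehicle than in the other groups, and Ifit1 is lowest in WT vehicle.

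The fifth comparison sets DPM against WT with E2. Immunoglobulin genes stood highest, Ighm by 3.34 and Igkv8-30 by 2.71, with errors of at most 2.18 and 1.81. Scgb1a1 (at least 2.30) and Bpifa1 (at least 1.93) remained higher, followed by Cap1 (1.84), Krt19 (1.42), Limd2 (1.37), Cd53 (1.24), Tpbg (1.14), Erdr1 and Prg4 (1.01). These genes were ranked by size alone, without regard to their errors. A large size therefore does not set a gene apart from 0. Leukocyte genes were higher in 15 of 17 cases, with a median of 0.47, and all 7 measured mesothelial and epithelial genes were higher, with a median of 0.72; Krt18 was higher by 0.72 with an error of at most 0.25. Endothelial genes were lower in 17 of 19 cases, with a median of -0.25 (5' controls: Gapdh -1.09 and beta-actin -0.09), among them Flt1 at -0.75 (error at most 0.26). The interferon median was -0.04, and that of the cardiac list 0.49.

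Lower in DPM with E2 were Cd99 (-1.24), Sema3f (-1.07), Dapk2 (-0.99), Rasip1 (-0.98), a gene of endothelial tube formation, Car9 (-0.98), Mylk2, Fubp1, Kcnab1, Palm, Zfp395, Bcam and Nes (-0.85, error at most 0.19), which encodes nestin. They too were ranked by size alone. Pik3r1 was lower at -0.80 with an error of at most 0.28, and Eno2 higher by 0.94 with one of at most 0.23. At 1.5-fold 60 genes were higher and 52 lower (43 and 62 centred, 47 and 54 quantile normalized). With the bounded error 74 genes had an unadjusted p under 0.05 and 0 passed when adjusted, with a smallest adjusted p = 0.0529. As in vehicle, a count from the bound is not comparable with the 257.6 that chance gives for a deposited p.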

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

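All tests in the part on explanations below were chosen after the results were seen. A test of the difference between the responses was passed by 5 genes, Siah1a over all genes and the others only when adjusted over a single list. No adjustment was made across lists, and none of those others passed over all genes. For this difference 216 genes had an unadjusted p under 0.05 by the deposited limma p, where chance gives 257.6. The 5 calls are therefore not established differences. Siah1a had a response higher in DPM by 0.17 (adjusted p = 0.0454 over all genes, limma). Its WT levels were equal within 1e-06, as they were for 4 genes in all. Equal levels in 2 groups can mark a probe set's own lowest level, so its small SE may understate the spread. The Siah1a call ended when centred or quantile normalized (smallest adjusted p = 0.389 and 0.336 of any gene). Flt1 had a response lower in DPM at -1.23 (adjusted p = 0.049 over the endothelial list alone). Ifit2 (-1.50), Ifit3 (-1.81) and Rsad2 (-1.67) passed when adjusted over the interferon list alone (adjusted p = 0.0434 each).

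Interferon genes had opposite medians in both genotypes, 0.30 in WT and -0.44 in DPM, and the DPM vehicle group stood highest and the WT vehicle group lowest. Heart and airway genes also stood highest in the DPM vehicle group. A change in leukocyte content as a whole is argued against for the DPM response, since the leukocyte list stood at 0.26 there while the interferon list went down. In that list 13 genes were higher and 4 lower, among them C1qa (-1.17) and C1qb (-0.22). A change in which leukocytes were present was not tested. Leukocyte content stays open for the WT response (0.14) and for DPM against WT in vehicle (0.13), where the leukocyte list shared the interferon list's sign with smaller medians. Pools of a group might differ in interferon state whatever the treatment: the list's median error lay at the 98.7 percentile of matched lists, but 12 of 21 lists lay above that bound, so this measure does not separate the lists. An effect of the peptide on the response to E2 also stays open, with 6 members at an unadjusted p under 0.05 for the difference. These open explanations cannot be told apart, because separate arrays were not analysed here.

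Heart muscle genes stood far higher in the DPM vehicle group than in the other 3, with a list median of 3.03 above WT vehicle. That median leans upwards, since most measured members passed the filter on level through the DPM vehicle group alone. Ventricular muscle is argued against, since the highest of Myl2, Myl3 and Myh7 stood at 2.62, near the lowest level of the array, where Nppa stood at 6.81 and Myl7 at 7.21. Atrial muscle or the muscle sleeve of vessels near the heart, present in part of the arrays of that group, stays open: the list's median error lay at percentile 100 of matched lists, but so many lists lay above the bound that this measure does not separate them, and 1 error shared by all groups points to none of them. An effect of genotype in both treatments stays open as well, since the list stood at 0.49 above WT with E2 against 3.03 with vehicle, and with no member past the threshold for E2 against vehicle in DPM these cannot be told apart.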

How the results depend on the processing

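The requirement of both an unadjusted p under 0.05 and 1.5-fold, the added noise and the correlation without the cardiac list were chosen after the data were seen. Counts of genes of at least 1.5-fold stayed within 1.5 times their values under centring, quantile normalization, the mean over probe sets and the removal of probe sets with shared sequence, ranging from 87 to 118 for the WT response and from 150 to 205 for the DPM response. A minimum level of 7 gave 52 genes for WT, 61 for DPM, 105 for the difference between the responses, 58 for DPM against WT in vehicle and 26 for that in E2. Adding 32 on the linear scale gave 46, 73, 116, 63 and 23 genes in the same order, and a 2-fold threshold gave 21, 42, 77, 46 and 13. With no filter on level, where more genes are tested, the difference had 555 genes and DPM against WT in E2 had 173. In DPM, centring turned the split from 116 higher and 87 lower to 69 and 123.

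At an adjusted p under 0.05 in WT, the minimum level of 7 and the removal of probe sets with shared sequence each gave 1 gene, Mast2, in place of 0; fewer genes were then tested. In DPM the count of 1 became 0 at a level of 7, 2 without shared-sequence probe sets (Rusc1 and Siah1a), and 0 under centring and 0 under quantile normalization. For the difference the count of 1 became 0 with no filter, 0 at a level of 7, 2 without shared-sequence probe sets, 0 centred and 0 quantile normalized. Siah1a lies below a level of 7, and both scalings move a fold whose SE is 0.01. At an unadjusted p under 0.05 the counts were 350, 268 and 216, and with 1.5-fold as well 75, 65 and 75. Noise that brought the WT errors up to those in DPM gave a median of 320 genes in WT over 100 draws (290 to 349), with 0 draws at or below the count in DPM, and 71 at an unadjusted p under 0.01 (57 to 90, 4 draws). That noise was drawn gene by gene and leaves out variation shared by the genes of an array. It therefore cannot show why the DPM count is lower. The correlation of the responses across genes, 0.135, became 0.232 at a level of 7, 0.614 over genes with an unadjusted p under 0.01 in WT 0.426 over those in DPM and 0.118 without the cardiac list; the cause was not tested.

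All 172 differences of the named genes kept their sign under centring, quantile normalization and the added 32. That was largely fixed in advance, since the genes were picked for a large fold or a low p. Centring removed medians of only 0.01 in WT, 0.08 in DPM and 0.07 for the difference. The added 32 cannot turn the sign of a difference between 2 groups. The mean over probe sets kept 142 of the 142 it could give. Tmod1, Lmo2 and Zfp35 in DPM passed an unadjusted p of 0.01 as deposited and no longer did when centred, at 1.09, 0.53 and 0.58. The mean over probe sets and the added 32 give no p. No paired analysis was possible because separate arrays were not analysed here and the group columns carry no replicate numbers. Leaving out each array and the replicate number as a block were not run for the same reason. Genes near the lowest level carry little signal over background, which limits Esr1, Esr2 and Strn, and also Nppa, Tnni3, Scgb1a1, Bpifa1 and Scgb3a2 in the groups where they lie at the lowest level.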

Other observations

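Of the 14 measured clock genes, 8 were higher and 6 lower in DPM vehicle than in WT vehicle. In DPM vehicle, Dbp (1.48), Nr1d1 (0.98), Tef (0.74) and Nr1d2 (0.70), which are driven by the clock's activating arm, stood higher than in WT vehicle. Arntl (-1.15) and Clock (-0.60), which encode that arm, and Nfil3 (-0.35) stood lower. With E2, 4 of the 14 were higher and 10 lower in DPM: Arntl stood at -0.02, Clock at -0.00, Dbp at -0.13, Tef at 0.03 and Nr1d2 at -0.12, while Nr1d1 stood at -0.67 and Nfil3 at 0.50. The errors of these differences are at most 1.75 for Dbp and 1.26 for Arntl, so no single gene is set apart from 0, and the median error of the 14 clock genes in WT, 0.35, lay above that of all 10000 matched lists. These genes were singled out after their values were seen.

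The families that follow were picked by symbol after the values were seen. Of 16 collagen chain genes, 12 were lower with E2 in WT and 14 in DPM, with medians of -0.11 and -0.10, and none had an unadjusted p under 0.05 by limma. Of 42 cytosolic ribosomal protein genes, 35 were higher with E2 in WT and 34 in DPM, with medians of 0.06 and 0.09, against 0.01 and 0.08 for all genes. Of 58 mitochondrial ribosomal protein genes, 51 were higher with E2 in DPM (41 when centred) and 28 in WT; 10 had an unadjusted p under 0.05 upwards in DPM (6 when centred) and 5 downwards in WT. The difference between the responses was 0.22 in the median and 0.15 when centred. Airway genes were singled out in the same way: Scgb1a1 stood at 6.43 in DPM vehicle, 4.61 in DPM with E2 and 2.32 in WT vehicle, while of the alveolar genes Sftpd stood at 3.74 in DPM vehicle, Sftpa1 at 2.41, both near the lowest level of the array in the other groups, and Sftpb and Sftpc at or under 2.36 in all groups.

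All tests of the pattern that follows were chosen after the result was seen. Of 69 respiratory chain genes, 60 were higher with E2 in DPM, 52 when centred, with a median of 0.17 (0.09 centred), and the 4 with an unadjusted p under 0.05 became 0 when centred. The family's median was -0.00 in WT, and -0.11 in vehicle for DPM relative to WT. A shared shift of genes with a short genomic span is argued against, since that length and the DPM response had a Spearman correlation of -0.011 across genes. Among random lists matched on that length the family's median lay at the 99.8 percentile, though the family was picked after its values were seen. Transcript length and the distance of probe sets from the 3' end were not tested. A difference in fat around the aortas stays open: the adipocyte list shared the family's sign at 0.24 in the DPM response and -0.35 in vehicle, but it stood at -0.16 in the WT response, where the family, with 33 genes higher and 36 lower, did not follow. A response of mitochondrial genes as a class stays open too: mitochondrial ribosomal protein genes lay at the 98.2 percentile in the DPM response and the 99.8 percentile in the difference, but inside the bounds in vehicle, and the family was picked after its values were seen. These cannot be told apart. No test here separates fat content from a response of fat cells or of vessel wall to E2.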
